A study of Cannabis sativa with 10 samples.

How the data were processed

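Messenger RNA from apical shoot tips of 1 Cannabis sativa genotype was measured in 10 libraries, 2 in each of 5 groups: vegetative, female week 1, male week 1, female week 3 and male week 3. Per the labels' protocols, total RNA was extracted with a column kit including a DNase step, its integrity was examined on agarose gels, and a sequencing company made Illumina libraries. Groups and replicate numbers were taken from the labels. The read length, aligner, counting tool, normalisation and statistical tool are not given in the sources used here.

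The deposited table has 1 line per gene and lists 35192 genes after 2 emptied lines were left out. Per the file headers, genes come from assembly ASM2916894v1, and coordinates, product descriptions and the closest Arabidopsis protein are those of the table. The values per library deposited by the authors are not named by a unit, and were read as FPKM from the values: totals differ between libraries, and the low values of a gene are multiples of a step that depends on gene and library. FPKM cannot be told apart from RPKM here. The table also holds, per the file headers, the authors' log2 fold change for each pair of groups, the p-value and adjusted p-value of that comparison, and the percent identity to the Arabidopsis protein. The authors' log2 fold changes and p-values were used only to be set beside the limma calls. All per-sample columns were used. Gene symbols were matched to the reference gene table of the same assembly for 34658 genes. A product description was present for 28745 genes, and for 16909 it named a product; 25053 genes had an Arabidopsis match, and 10910 were listed at 0 in all libraries.

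The depth in reads is unknown. Totals of FPKM in replicates 1 and 2 were 706260 and 750743 in vegetative, 734508 and 712463 in female week 1, 736178 and 731665 in male week 1, 630805 and 603616 in female week 3, and 736053 and 764672 in male week 3 libraries. Depth relative to female week 1 replicate 1, estimated from genes with values between 0.001 and 0.4 FPKM, was 1.011 and 0.908, 1.000 and 1.031, 0.979 and 0.862, 1.226 and 1.235, and 0.909 and 0.903 in the same order. The 10 highest genes held 4.41% to 8.03% of each total. Without counts, no counting interval can be given, and values near 0 are imprecise.

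The comparisons, tests, named genes, gene lists and alternatives were chosen before the data were examined. The design assumed counts; the table holds FPKM, so the test written for normalised values was used. Genes with a mean of at least 1 FPKM in at least 1 group (18309) were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 10 libraries and no other term. The fit had 5 residual and a median of 4.63 prior degrees of freedom, and empirical Bayes moderation with a trend and robust estimation. The 8 comparisons between groups and the interaction were contrasts of this fit, 2-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. After an exploratory fit, 5 simulations of male against female week 1 used fitted means and spread. Of 250 genes per change of 1, 2, 3 and 4 log2 units, 90%, 100%, 100% and 99.6% were called, and 58 of 90295 unchanged. Real recovery may be lower, as groups shared 1 spread, male week 1 varied most and adjustment is stricter with few changes.

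Gene lists, 19 in all, were matched on product descriptions and Arabidopsis matches: floral MADS-box; flowering time and inflorescence identity; stamen and pollen wall; pollen and pollen tube cell wall; gynoecium and ovule; ethylene; gibberellin; auxin; cytokinin; jasmonate; cannabinoid and terpene; flavonoid; lipid transfer; meristem homeobox; cell cycle and histones; photosynthesis; circadian clock; heat shock; metal and glutathione. Search terms were adapted to the wording of the descriptions before any fit. As an exception, 1 circadian term was narrowed after results had been seen because it also matched 2 auxin genes. Lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over 171 tests (19 lists, 9 contrasts). Of 67 calls, 4 held with an estimated correlation, all of the stamen and pollen wall list (male week 3 against female week 3, male week 1 and vegetative apices, and the interaction).

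Named genes followed a rule: for each list and comparison up to 4 called members with the largest absolute log2 fold change, or the member with the highest mean where none was called; the 8 called genes with the largest rises and the 8 with the largest falls among genes whose groups did not overlap, whose higher group had a mean of at least 10 FPKM (written for CPM) and whose description named a product; floral MADS-box genes whatever their result; and 5 genes of each direction in the interaction. The text gives a subset from the top of each ranking. Overlaps of calls were compared with the product of the list sizes over the genes tested and, at week 1, with Fisher's exact test. Where 2 comparisons shared the vegetative libraries, 100 simulations of unchanged groups with the fitted spread were compared with the observed overlap.

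The alternatives were a pseudocount of 0.1, no filter on low values, the replicate number as a block, a fit of only the groups compared, leaving out each library in turn, a log2 fold change of at least 1, and, for lists, an estimated correlation and fry. Scaling by median ratios (factors of 0.954 to 1.004 over 14753 genes) and scaling to equal totals were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.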

Results

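Messenger RNA was sequenced from apical shoot tips of Cannabis sativa, a species that usually bears male and female flowers on separate plants. All 10 libraries came from 1 genotype, named A3, and fell into 5 groups of 2 libraries: vegetative apices, female and male apices at week 1 of flowering, and female and male apices at week 3. Male flowers had been induced with a treatment given in the labels as STS, read here as silver thiosulfate, a compound that blocks ethylene perception and makes female cannabis plants form male flowers. The labels name this treatment for every male library and for no female or vegetative library, so a difference between male and female below is also a difference between treated and untreated plants. Gene levels were FPKM, a fragment count normalised for gene length and library depth. Totals of FPKM ran from 603616 in female week 3 replicate 2 to 764672 in male week 3 replicate 2. The depth in reads is unknown, and depth relative to female week 1 replicate 1, estimated from low values, ran from 0.862 to 1.235. Of 35192 genes, 18309 reached a mean of 1 FPKM in at least 1 group and were tested with limma. Levels are given as mean ± SD in FPKM (n = 2 libraries), and fold changes as log2 differences ± SE on the log2(FPKM + 1) scale, which understates the change of low genes. The largest rises and falls given below are those among genes with a described product, at least 10 FPKM in the higher group and no overlap between the libraries compared. The p-values measure only the spread between these samples, which may be technical, since the labels do not say that replicates are separate plants.

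The 2 libraries of each group resembled each other closely, with Pearson correlations of log2 levels across genes of 0.988 in vegetative, 0.990 in female week 1, 0.980 in male week 1, 0.992 in female week 3 and 0.980 in male week 3 apices. Female and male week 1 libraries correlated between 0.976 and 0.990, a range that overlapped the range within groups. A male library was thus closer to a female one, at 0.990, than the male week 1 libraries were to each other, at 0.980. Male week 3 libraries stood apart, with correlations of 0.722 to 0.742 with the other groups. The first principal component held 72.0% of the variance and separated male week 3 from all other libraries, and the second held 16.3% and separated female week 3. The difference between the 2 replicates had an SD of 0.416 log2 in male week 1 against 0.290 in female week 1, and 338 against 92 genes lay more than 1 log2 unit apart.

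**Figure D1:**
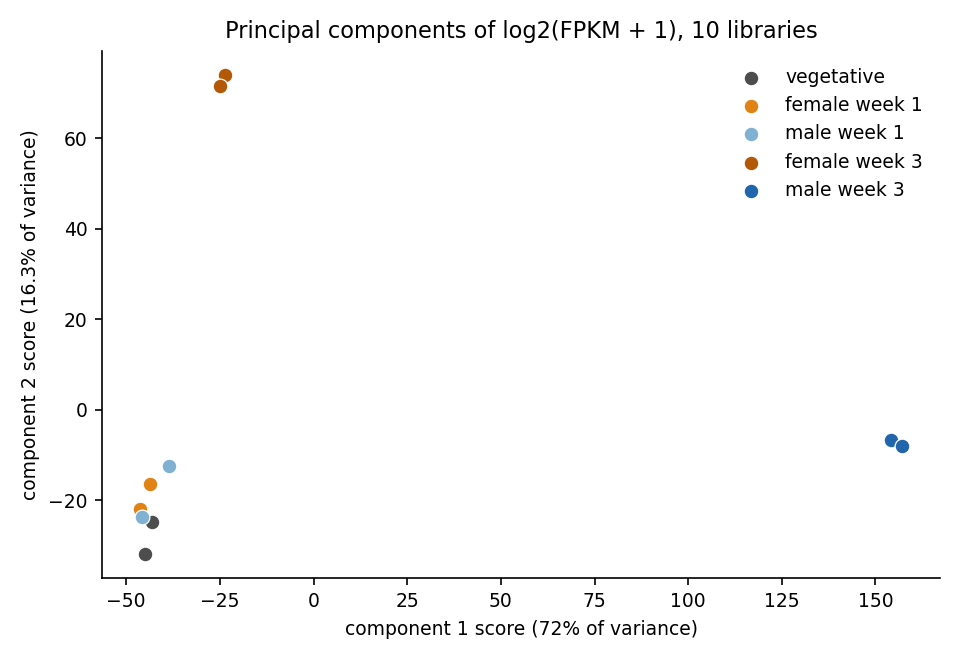
Scores of the 10 libraries on the first and second principal components of log2(FPKM + 1) over the 18309 tested genes, with the share of variance on each axis; each point is a library, coloured by group. Both male week 3 libraries lie at 154.2 or more on the first component and both female week 3 libraries at 71.6 or more on the second, while vegetative and week 1 libraries lie together.

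The title of the series names MADS-box genes, the transcription factors that specify floral organs, and 20 of them were tested whatever their result. Apices at week 1 had 2 of these genes far above the vegetative level. The gene described as CAULIFLOWER (LOC115704295; chromosome X, 84790432 to 84794420, build ASM2916894v1), whose closest Arabidopsis protein was AGL16 at 48.88% identity, was at 2.48 ± 1.82 FPKM in vegetative, 140 ± 30.1 in female week 1 and 165 ± 63.1 in male week 1 apices. CAULIFLOWER A (LOC115702300; chromosome 3, 69985219 to 69994540), closest to FRUITFULL, which promotes flowering, went from 0.188 ± 0.266 to 45.3 ± 6.3 in female and 47.6 ± 11.5 in male week 1 apices. The genes closest to those of stamen identity were high in male week 3 apices. TM6 (LOC115714657; chromosome 4, 78054032 to 78057013), closest to APETALA3, was at 163 ± 9.95 FPKM in male week 3 and 0.0977 ± 0.0826 in female week 3 apices. PMADS 2 (LOC115699531; chromosome 8, 48462703 to 48465748), closest to PISTILLATA, was at 119 ± 10.2 against 0.116 ± 0.164. APETALA3 and PISTILLATA together specify petals and stamens. A gene described as AGAMOUS (LOC115700192; chromosome X, 81938054 to 81940559), with only 32.0% identity to AGL11, was at 270 ± 22.2 against 2.63 ± 0.354. A different AGAMOUS gene (LOC115697576; chromosome 7, 61415108 to 61423167), with 63.64% identity to Arabidopsis AGAMOUS, which specifies stamens and carpels, was present in both sexes at week 3, at 77.5 ± 15.6 in female and 37.7 ± 3.99 in male apices. AGL11 (LOC133031811; chromosome X, 71236908 to 71244796), closest to the ovule identity gene SEEDSTICK, was at 9.16 ± 1.41 in female and 8.22 ± 1.97 in male apices at week 1, then at 76.8 ± 9.9 in female and 1.01 ± 0.226 in male apices at week 3. MADS4 (LOC115712087; chromosome 4, 12387288 to 12398632), closest to SEPALLATA3, a partner of the other floral MADS proteins, was at 75.1 ± 12.4 in female and 35.5 ± 2.97 in male week 3 apices and at 0.575 ± 0.418 in vegetative apices.

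**Figure D2:**
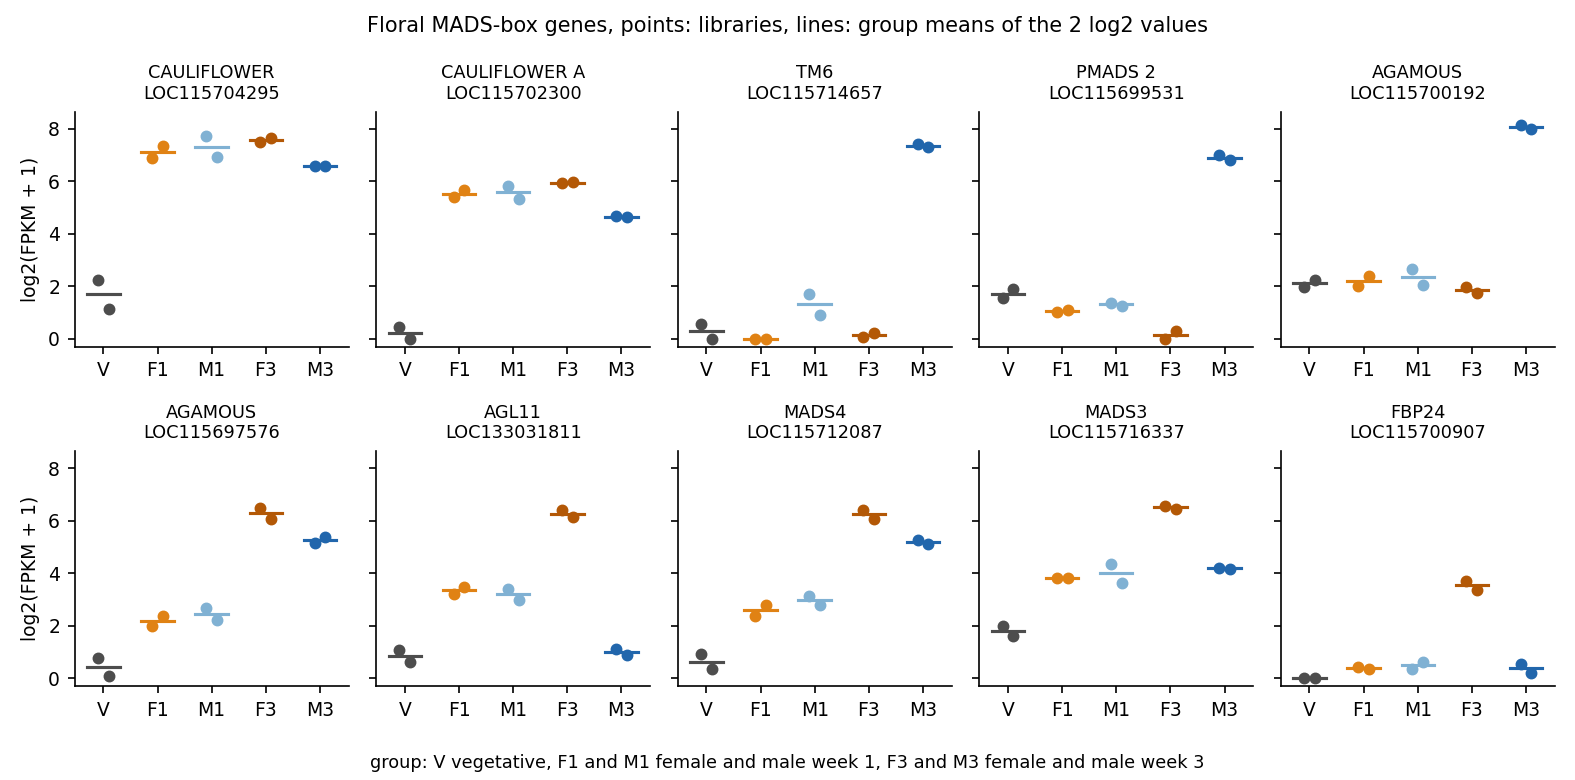
Levels of 10 floral MADS-box genes as log2(FPKM + 1) in each of the 5 groups, with 1 point per library and a line at the mean of the log2 values. TM6, PMADS 2 and the AGAMOUS gene LOC115700192 are high in male week 3 alone, with means of 163, 119 and 270 FPKM, and AGL11, MADS3 and FBP24 are highest in female week 3, with means of 76.8, 90.1 and 10.6 FPKM.

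Week 1 and vegetative apices, compared here, may differ in harvest or handling besides flowering. In female week 1 apices the largest rises were CAULIFLOWER, by 5.43 ± 0.34 log2 (adjusted p = 6.73e-05), and CAULIFLOWER A, by 5.30 ± 0.19 (adjusted p = 3.36e-06). Major latex allergen Hev b 5 (LOC115700445) rose by 3.93 ± 0.23, from 9.5 ± 0.0828 to 161 ± 35.4 FPKM, and early nodulin-75 (LOC115722790) rose by 3.05 ± 0.58. The largest falls were a polygalacturonase inhibitor-like gene (LOC115699588), from 55.6 ± 4.91 to 1.04 ± 0.266 FPKM (log2 change -4.80 ± 0.21), and 2 heat shock genes. Heat shock protein 83 (LOC115706731) went from 38.4 ± 11.4 to 0.707 ± 0.0619 and mitochondrial heat shock 22 kDa protein (LOC115707101) from 66.2 ± 32.9 to 1.91 ± 0.431. A gene described as a salicylate and benzoate methyltransferase (LOC115711939), an enzyme that makes volatile methyl esters, fell by 3.51 ± 0.22 from 34.8 ± 4.68 to 2.15 ± 0.468 FPKM. Early nodulin-75 was not called with 1 library left out in 2 of 4 cases, at adjusted p = 0.181 without female week 1 replicate 1 and 0.173 without female week 1 replicate 2.

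Of the 20 floral MADS-box genes, 11 rose and 1 fell, and 8 did not pass the test (13 higher and 2 lower adjusted over the list alone). The median log2 fold change was 1.01, above the other genes in camera (adjusted p = 4.15e-10; adjusted p = 0.335 with an estimated correlation). Beside the CAULIFLOWER genes, AGL11 rose by 2.50 ± 0.22, MADS3 (LOC115716337), closest to AGL6, by 2.01 ± 0.22, and the AGAMOUS gene LOC115697576 by 1.75 ± 0.26, whereas LOC115725163, described as CAULIFLOWER A but closest to MAF4, a repressor of flowering, fell by 0.91 ± 0.17. Of the 101 cell cycle and histone genes, 38 rose, and 63 did not pass the test (43 higher adjusted over the list alone). With a median of 0.23, the list lay above the other genes at a camera adjusted p of 2.23e-10 (adjusted p = 0.443 with an estimated correlation). Histone H1 (LOC115700925) went from 142 ± 22.1 to 401 ± 56.8 FPKM and histone H2B.7-like (LOC115701469) from 207 ± 52.2 to 549 ± 49.1. Among 61 heat shock genes, 2 rose and 20 fell (3 and 22 adjusted over the list alone), with a median of -0.23 and camera adjusted p = 3.18e-09 (adjusted p = 0.215 with an estimated correlation). Across 47 jasmonate genes, 1 rose and 9 fell (1 and 16 adjusted over the list alone), with a median of -0.23 and camera adjusted p = 2.03e-06 (adjusted p = 0.215 with an estimated correlation). Linoleate 13S-lipoxygenase (LOC115719616), of the pathway that begins jasmonate synthesis, fell by 1.87 ± 0.38. Of 48 photosynthesis genes, 1 rose and 5 fell (1 and 8 adjusted over the list alone), with a median of -0.11 and camera adjusted p = 0.0155 (adjusted p = 0.764 with an estimated correlation). Chlorophyll a-b binding protein 151 (LOC115712676) went from 2320 ± 149 to 854 ± 157 FPKM. Among 92 pollen and pollen tube cell wall genes, 8 rose (15 higher and 1 lower adjusted over the list alone), with a median of 0.10 and camera adjusted p = 0.00279 (adjusted p = 0.383 with an estimated correlation). The members with the largest rises were pectin enzymes, polygalacturonase At1g48100 (LOC115713183), by 1.47 ± 0.18, and a probable polygalacturonase (LOC115706421), by 1.32 ± 0.13. No member of the 33 meristem homeobox genes passed the limma test, with 11 at an unadjusted p under 0.05 (5 higher adjusted over the list alone). The median log2 fold change of the list was 0.15, and camera placed it above the other genes at adjusted p = 0.00496 (adjusted p = 0.397 with an estimated correlation). In the flowering time list 6 rose and 3 fell (11 and 4 adjusted over the list alone), and camera made no call. The member bZIP transcription factor 27 (LOC115722367), of the FD family that acts with FLOWERING LOCUS T, rose by 2.96 ± 0.22. JOINTLESS (LOC115714329), closest to SVP and AGL24, of which SVP represses flowering, fell by 2.05 ± 0.16. FLOWERING LOCUS T (LOC115709185) was at 2.42 and 1.74 FPKM in the female libraries and listed at 0 in both vegetative libraries (adjusted p = 0.0354). CRABS CLAW (LOC115699020), a carpel regulator, rose by 1.74 ± 0.24 and dihydroflavonol 4-reductase (LOC115710150), of anthocyanin synthesis, rose by 1.81 ± 0.30. PRR95 (LOC115705125), a clock component, fell by 1.57 ± 0.19. Some of these calls were lost with 1 library left out. The adjusted p of the AGAMOUS gene became 0.058 without female week 1 replicate 2, and of histone H2B.7-like 0.0687 without female week 1 replicate 2 and 0.0545 without vegetative replicate 2. That of dihydroflavonol 4-reductase became 0.0801 without female week 1 replicate 2 and that of linoleate 13S-lipoxygenase 0.137 without female week 1 replicate 2, 0.0527 without vegetative replicate 1 and 0.148 without vegetative replicate 2. With any 1 of the 4 libraries left out, FLOWERING LOCUS T had an adjusted p of 0.118 to 0.208 and LOC115725163 one of 0.0609 to 0.113.

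In all, 904 genes changed in female week 1 against vegetative apices at adjusted p under 0.05 in limma, 488 higher and 416 lower, and 389 of them by at least 1 log2 unit. Leaving out a library lowered this count to 502 without vegetative replicate 1, 401 without vegetative replicate 2, 312 without female week 1 replicate 1 and 230 without female week 1 replicate 2, and a fit of only these groups gave 394.

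Male week 1 apices differed from vegetative apices in many of the genes that changed in female apices. CAULIFLOWER rose by 5.63 ± 0.34, CAULIFLOWER A by 5.35 ± 0.19 and Hev b 5 by 4.70 ± 0.23, to 277 ± 80.6 FPKM. Next came DMR6-LIKE OXYGENASE 2 (LOC115715781), related to the salicylate hydroxylases, from 1.84 ± 1.46 to 67.7 ± 28.9 FPKM (log2 change 4.63 ± 0.36). The largest falls were the polygalacturonase inhibitor-like gene LOC115699588, which fell by 5.21 ± 0.21 log2, heat shock 22 kDa protein, to 1.54 ± 0.645 FPKM, and heat shock protein 83, to 0.787 ± 0.156 FPKM. They were followed by a root isozyme of ferredoxin-NADP reductase (LOC115695589), from 12.8 ± 0.611 to 0.726 ± 0.133 FPKM. Across 20 floral MADS-box genes, 12 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 1.01 and camera adjusted p = 4.77e-12 (adjusted p = 0.332 with an estimated correlation). TM6 was at 1.55 ± 0.935 FPKM and rose by 1.02. Of 101 cell cycle and histone genes, 42 rose and 2 fell (45 and 2 adjusted over the list alone), with a median of 0.33 and camera adjusted p = 1.57e-15 (adjusted p = 0.341 with an estimated correlation). Among 48 photosynthesis genes, 11 fell (1 higher and 18 lower adjusted over the list alone), with a median of -0.49 and camera adjusted p = 1.95e-09 (adjusted p = 0.578 with an estimated correlation). Its male replicates differed by more, a median of -0.57. Across 61 heat shock genes, 2 rose and 20 fell (2 and 24 adjusted over the list alone), with a median of -0.25 and camera adjusted p = 2.34e-08 (adjusted p = 0.215 with an estimated correlation). Of 47 jasmonate genes, 3 rose and 7 fell (3 and 9 adjusted over the list alone), with a median of -0.18 and camera adjusted p = 0.00261 (adjusted p = 0.335 with an estimated correlation). Among 33 meristem homeobox genes, 5 rose (9 adjusted over the list alone), with a median of 0.22 and camera adjusted p = 0.00329 (adjusted p = 0.383 with an estimated correlation). They included BEL1-like homeodomain protein 9 (LOC115720529), by 1.32 ± 0.24, and WUSCHEL-related homeobox 9 (LOC115697124), by 1.06 ± 0.18. The LEAFY homolog (LOC115695615), which confers floral meristem identity, went from 1.07 ± 0.0443 to 7.13 ± 1.86 FPKM, and CRABS CLAW rose by 2.09 ± 0.24. The adjusted p of TM6 became 0.18 without male week 1 replicate 1 and 0.263 without vegetative replicate 2, of BEL1-like homeodomain protein 9 0.0899 without vegetative replicate 2 and of WUSCHEL-related homeobox 9 0.055 without vegetative replicate 1.

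In all, 1172 genes changed in male week 1 against vegetative apices in limma, 649 higher and 523 lower, and 504 by at least 1 log2 unit. The count was 734 without vegetative replicate 1 and 658 without vegetative replicate 2, and a fit of only these groups called 8. Female and male week 1 apices shared 368 of the higher and 285 of the lower genes, where independent lists would share 17.3 and 11.9, and 1 gene was called in opposite directions. Both comparisons use the same vegetative libraries, and simulated unchanged groups against them shared 0.03 calls on average (2 at most) where 653 were observed. The covariance of log2 fold changes across genes was 0.1294 against 0.0243 in the simulations, and the correlation 0.792 against 0.495; genes are not independent replicates. With the vegetative libraries split, 1 for each sex, 244 and 298 genes were shared in the 2 ways of splitting, 125 and 173 higher (4.3 and 4.9 expected) and 119 and 125 lower (3.6 and 4.1 expected), with 2 and 3 called in opposite directions. The covariance was then 0.1013 and 0.1045 and the correlation 0.532 and 0.553, so genes were also shared without a common control library.

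Male and female apices at week 1 differed in few genes, led by genes known from salicylate defence. DMR6-LIKE OXYGENASE 2 (LOC115715781; chromosome 5, 68290867 to 68292879) was at 67.7 ± 28.9 against 0.155 ± 0.148 FPKM (log2 difference 5.83 ± 0.36, adjusted p = 0.000185). WRKY70 (LOC115707511; chromosome 1, 616472 to 619300), a transcription factor of salicylate-dependent defence, was at 30.2 ± 6.86 against 1.06 ± 0.498 FPKM (log2 difference 3.93 ± 0.25, adjusted p = 0.000185), and another gene of that description (LOC115695993) at 11.8 ± 0.306 against 3.35 ± 1.6. NIM1-INTERACTING 2 (LOC115712507), which binds the salicylate coregulator NPR1, was at 34.7 ± 24.9 against 2.16 ± 0.979, and DOWNY MILDEW RESISTANCE 6 (LOC115717114), a salicylate hydroxylase, at 38.5 ± 0.502 against 6.67 ± 1.01. Wall-associated receptor kinase-like 1 (LOC115719063) was at 22.2 ± 3.57 against 3.1 ± 1.21, probable nucleoredoxin 1 (LOC115712631) at 153 ± 9.88 against 40.9 ± 0.825 and the salicylate and benzoate methyltransferase LOC115711939 at 12.4 ± 3.28 against 2.15 ± 0.468 FPKM. The log2 differences of these 5 genes were 3.33, 2.37, 2.52, 1.87 and 2.08. Lower in male apices was RADIALIS-like 2 (LOC115713090), a MYB protein, at 8.31 ± 0.539 against 18.7 ± 0.401 FPKM (log2 difference -1.08 ± 0.13, adjusted p = 0.0203). DMR6-LIKE OXYGENASE 2, WRKY70 LOC115707511 and nucleoredoxin 1 stayed below 0.05 with any 1 of the 4 libraries left out. The other calls were less firm. Without female week 1 replicate 1, the adjusted p was 0.148 for NIM1-INTERACTING 2, 0.0694 for DOWNY MILDEW RESISTANCE 6, 0.0694 for wall-associated receptor kinase-like 1, 0.0694 for the methyltransferase and 0.111 for RADIALIS-like 2. Without female week 1 replicate 2, it was 0.0836 for NIM1-INTERACTING 2, 0.191 for DOWNY MILDEW RESISTANCE 6, 0.253 for wall-associated receptor kinase-like 1, 0.0543 for the methyltransferase, 0.253 for WRKY70 LOC115695993 and 0.191 for RADIALIS-like 2. Without male week 1 replicate 1, it was 0.0518 for DOWNY MILDEW RESISTANCE 6, 0.115 for wall-associated receptor kinase-like 1 and 0.14 for WRKY70 LOC115695993. Without male week 1 replicate 2, it was 0.0579 for WRKY70 LOC115695993.

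The remaining called genes were not named by rule in this comparison and are given, chosen after their values were seen, because they are few. Higher in male week 1 were NRT1/PTR family 5.5-like (LOC115697546, log2 difference 1.70), acidic endochitinase (LOC115705896, 1.63), glucan endo-1,3-beta-glucosidase (LOC115710100, 1.59), and lysine histidine transporter-like 7 (LOC115701257, 1.49). So were pleiotropic drug resistance protein 3 (LOC115712604, 1.48), mannitol dehydrogenase (LOC133037330, 1.27), an early light-induced protein (LOC115722853, 1.14), sucrose synthase (LOC115705483, 1.10) and mulatexin (LOC115711958, 1.06). A PR1-like gene (LOC133031825), of a family of pathogenesis-related markers, was at 1.58 and 3.29 FPKM in male and listed at 0 in female libraries. LOC115708487, which has no description, was at 44.2 and 33.1 FPKM in male week 1 and listed at 0 in the other 8 libraries. LOC133033235 (1.81) and LOC115700763 (1.36) were also higher. LOC115703305 was at 2.24 and 2.17 FPKM in female and listed at 0 in male libraries. The ferredoxin-NADP reductase LOC115695589 was at 0.726 ± 0.133 FPKM in male against 8.54 ± 2.49 in female apices (log2 difference -2.44).

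Of the 47 jasmonate genes, 1 was higher, and 46 did not pass the test (5 higher adjusted over the list alone). The median was 0.03 and camera gave adjusted p = 0.072. The member called was a lipoxygenase 2 (LOC115720530), at 70.3 ± 0.11 against 35.2 ± 6.66 FPKM and 68.7 ± 4.11 in vegetative apices, with an adjusted p of 0.056 to 0.352 when any 1 of the 4 libraries was left out. No member of the 48 photosynthesis genes passed the limma test, with 2 at an unadjusted p under 0.05 (0 adjusted over the list alone). With a median of -0.34, the list lay below the other genes at a camera adjusted p of 1.07e-10 (adjusted p = 0.531 with an estimated correlation). Rubisco small subunit (LOC115714527) was at 6980 ± 3340 against 9420 ± 1670 FPKM and did not pass (adjusted p = 0.896); the replicates of male week 1 differed in this list by a median of -0.57 log2, replicate 1 minus replicate 2. No member of the 101 cell cycle and histone genes passed the limma test, with 7 at an unadjusted p under 0.05 (0 adjusted over the list alone). The median log2 fold change of the list was 0.15, and camera placed it above the other genes at adjusted p = 1.52e-06 (adjusted p = 0.531 with an estimated correlation). No member of the 20 floral MADS-box genes passed the limma test, with 3 at an unadjusted p under 0.05 (1 higher adjusted over the list alone). The median log2 fold change was 0.19, above the other genes in camera (adjusted p = 0.0491; adjusted p = 0.655 with an estimated correlation). In these 2 lists the male replicates differed by medians of 0.23 and 0.47, more than the medians between the sexes. TM6 was at 2.22 and 0.894 FPKM in the male libraries and listed at 0 in both female libraries (adjusted p = 0.132), and AGL11 and PMADS 2 did not pass the test. Ethylene, metal and glutathione, and stamen and pollen wall genes had medians of -0.01, 0 and 0 and no call in camera. ACC oxidase (LOC115699412), which makes ethylene, was at 86.5 ± 11 against 158 ± 20.3 FPKM (log2 difference -0.86 ± 0.14, adjusted p = 0.0717). TM6 and this ACC oxidase were called without male week 1 replicate 2, at adjusted p = 0.025 and 0.0339. Outside jasmonate, photosynthesis, cell cycle and floral MADS-box genes, no list had a member called in limma over all genes or a call in camera, and each had 0 to 8 members at an unadjusted p under 0.05. Adjusted over the list alone, 3 metal and glutathione genes were higher, and 1 ethylene, 1 cannabinoid and terpene and 1 stamen and pollen wall gene were lower.

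In all, 25 genes differed between male and female week 1 apices in limma at adjusted p under 0.05, 22 higher and 3 lower in male, and 1102 had an unadjusted p under 0.05. The count was 10 without female replicate 1, 5 without female replicate 2, 16 without male replicate 1 and 86 without male replicate 2 (57 higher, 29 lower). These fits shared 6, 4, 13 and 19 genes with the 25. A limma fit of only these 4 libraries called 0 at adjusted p under 0.05 and 835 at an unadjusted p under 0.05. With all genes kept the count was 5, with a pseudocount of 0.1 it was 16, with median-ratio scaling 17 (16 higher, 1 lower) and with libraries scaled to equal totals 18 (15 higher, 3 lower).

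**Figure D3:**
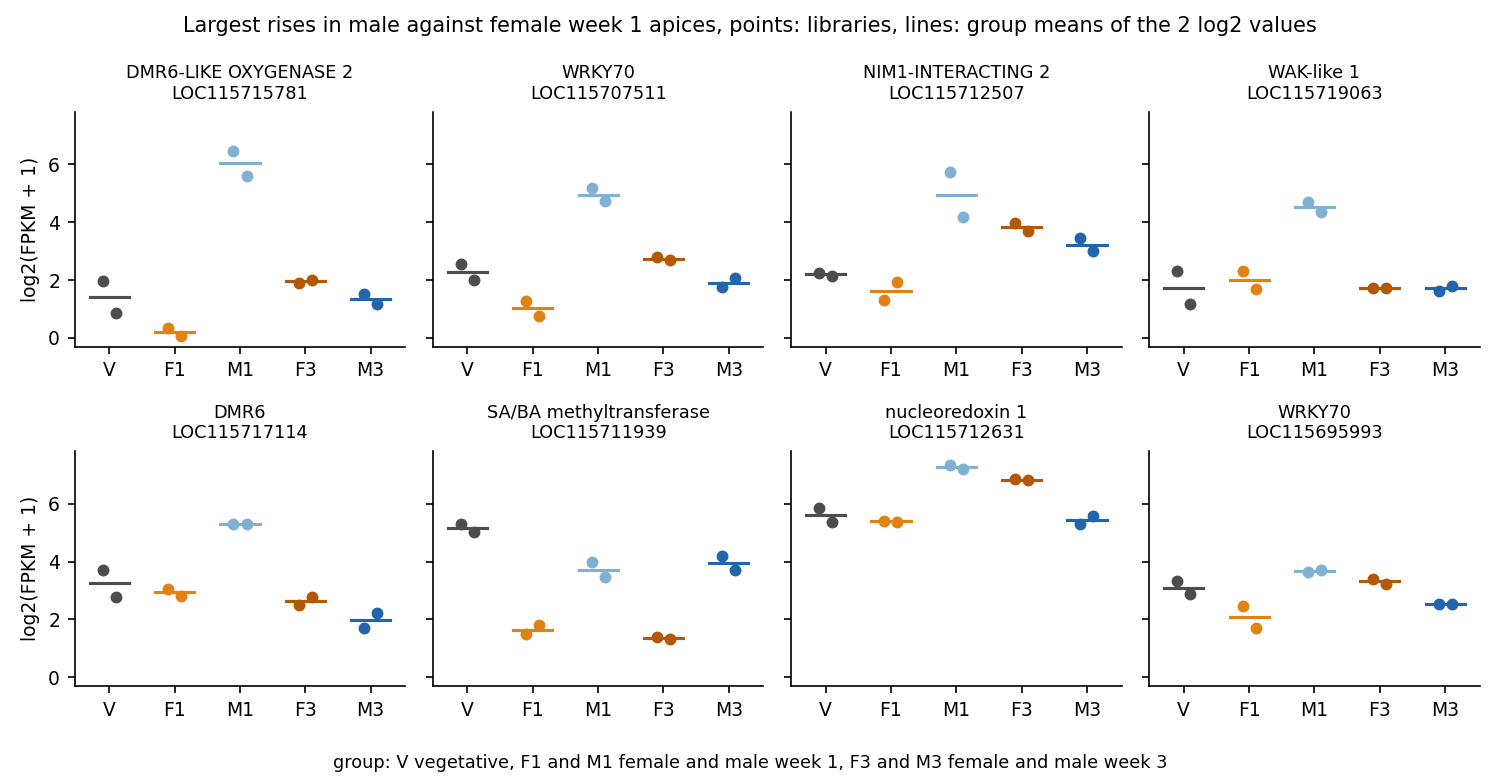
Levels of the 8 genes with the largest differences toward male apices at week 1, as log2(FPKM + 1) in each of the 5 groups, with 1 point per library and a line at the mean of the log2 values. DMR6-LIKE OXYGENASE 2 is at 67.7 FPKM in male week 1 and 0.155 in female week 1, and the methyltransferase LOC115711939 is highest in vegetative apices, at 34.8 FPKM.

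At week 3 male and female apices differed in most of the tested genes, and genes of the pollen wall were among those far higher in male apices. Type III polyketide synthase A (LOC115715682; chromosome 5, 27875864 to 27877387), which makes precursors of sporopollenin in the pollen wall, was at 543 ± 1.08 against 0.0848 ± 0.0597 FPKM (log2 difference 8.97 ± 0.15, adjusted p = 2.31e-10). 4-coumarate-CoA ligase-like 1 (LOC115712547) was at 589 ± 306 against 0.334 ± 0.186 and fatty acyl-CoA reductase 2 (LOC115699209) at 320 ± 148 against 0.188 ± 0.0258 FPKM, both of the same pathway. The gene with the largest difference was ATL6-like ubiquitin ligase (LOC115718105), at 3290 ± 35.8 FPKM in male and near 0 in female apices (log2 difference 11.68 ± 0.15). It was followed by MEN-8 (LOC115715872), by 11.32 ± 0.31 to 3270 ± 1500 FPKM, and M7 (LOC115718067), by 11.02 ± 0.31 to 2900 ± 887. Next came class V chitinase CHIT5-like (LOC115695573), by 10.64 ± 0.40 to 2270 ± 1310 and non-specific lipid-transfer protein A-like (LOC115707560) by 10.49 ± 0.23 to 1660 ± 611.

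Highest in female week 3 apices relative to male was non-specific lipid-transfer protein 1 (LOC115696872; chromosome 7, 2432294 to 2452827), at 884 ± 268 FPKM against 0.275 ± 0.004 (log2 difference -9.40 ± 0.20, adjusted p = 3.54e-10). Germin-like protein 1-17 (LOC115718819) was at 311 ± 12.5 against 0.632 ± 0.301, the antimicrobial peptide thionin (LOC115712639) at 3020 ± 499 against 20.3 ± 3.47 and MLP-like protein 34 (LOC133030054) at 132 ± 27.4 against 0.425 ± 0.0692. Across 10 gynoecium and ovule genes, 1 was higher and 7 lower (1 and 7 adjusted over the list alone), with a median of -1.58 and camera adjusted p = 0.0056 (adjusted p = 0.341 with an estimated correlation). CRABS CLAW was at 20.7 ± 2.95 in female and 0.607 ± 0.104 in male apices (log2 difference -3.75 ± 0.24) and AINTEGUMENTA (LOC115712812), which promotes organ and ovule growth, at 36.6 ± 0.183 and 6.02 ± 0.345. Of 41 cannabinoid and terpene genes, 27 were lower (27 adjusted over the list alone), with a median of -1.07 and camera adjusted p = 5.33e-06 (adjusted p = 0.215 with an estimated correlation). Geranyllinalool synthase (LOC115696242) was at 26.8 ± 2.74 FPKM in female and 0.752 ± 0.395 in male apices. Myrcene synthase (LOC115716605) had a log2 difference of -2.51 ± 0.20, and the geranyltransferase of cannabinoid synthesis (LOC115713215) was at 45.5 ± 4.81 FPKM in female and 7.37 ± 0.0873 in male apices. Among 38 flavonoid genes, 3 were higher and 25 lower (3 and 25 adjusted over the list alone), with a median of -0.98 and camera adjusted p = 3.55e-05 (adjusted p = 0.335 with an estimated correlation). Dihydroflavonol 4-reductase was at 722 ± 122 in female and 105 ± 19.5 in male apices and flavanone 3-dioxygenase (LOC115702709) at 124 ± 23.4 and 22.5 ± 1.21. Across 47 jasmonate genes, 4 were higher and 31 lower (4 and 31 adjusted over the list alone), with a median of -0.92 and camera adjusted p = 5.53e-06 (adjusted p = 0.215 with an estimated correlation). Log2 differences were -3.94 ± 0.25 for linoleate 9S-lipoxygenase 5 (LOC115709296) and -3.35 ± 0.14 for allene oxide synthase 3 (LOC115703186). Their part in jasmonate synthesis was not tested. Of 107 auxin genes, 17 were higher and 49 lower (17 and 49 adjusted over the list alone), with a median of -0.46 and camera adjusted p = 0.00512 (adjusted p = 0.266 with an estimated correlation). The top member was auxin-responsive protein IAA14 (LOC115722629), at 36.5 ± 3.69 in female and 2.33 ± 0.219 in male apices. Among 33 meristem homeobox genes, 4 were higher and 21 lower (4 and 21 adjusted over the list alone), with a median of -0.79 and camera adjusted p = 0.00135 (adjusted p = 0.341 with an estimated correlation). WUSCHEL-related homeobox 1 (LOC133036332) had a log2 difference of -2.22 ± 0.21 and BEL1-like homeodomain protein 9 (LOC115720529) was higher by 2.18 ± 0.24; WUSCHEL (LOC115711960), which maintains stem cells, was at 4.21 ± 2.2 FPKM in male and 0.303 ± 0.141 in female apices.

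Of the 22 stamen and pollen wall genes, 20 were higher, and 2 did not pass the test (22 higher adjusted over the list alone). With a median of 4.31, the list lay above the other genes at a camera adjusted p of 1.68e-11 (adjusted p = 0.037 with an estimated correlation). Across 20 floral MADS-box genes, 4 were higher and 12 lower (4 and 12 adjusted over the list alone), with a median of -1.03 and camera adjusted p = 0.0447 (adjusted p = 0.655 with an estimated correlation), or 0.172 scaled to equal totals. TM6 was higher by 7.22 ± 0.26 (adjusted p = 9.47e-09), PMADS 2 by 6.75 ± 0.17, the AGAMOUS gene LOC115700192 by 6.22 ± 0.22 and MADS2 (LOC115709018), closest to SEPALLATA2, by 1.82 ± 0.25. AGL11 had a log2 difference of -5.28 ± 0.22 (adjusted p = 2.41e-08). The ovule genes FBP24 (LOC115700907) and FBP24-like (LOC115707234), of the Bsister class, had log2 differences of -3.17 and -2.72. Log2 differences were -2.33 for MADS3 LOC115716337, -1.50 for MADS3 LOC115704294 and -2.06 for MADS1 (LOC115698701), closest to SHATTERPROOF1. They were -1.05 for MADS4, -1.01 for the AGAMOUS gene LOC115697576 and -0.98 for CAULIFLOWER LOC115704295, of which the last 2 were not firm. The adjusted p of this AGAMOUS gene became 0.0682 without female week 3 replicate 1 and 0.0637 without male week 3 replicate 1, and that of CAULIFLOWER 0.082 to 0.128 with any 1 library left out. The genes described as CAULIFLOWER A gave -1.31 for LOC115702300, -2.37 for LOC115698549, -2.49 for LOC115701144, and no call for LOC115701438 and LOC115725163. MADS2 LOC115700827 and LOC115700828, which overlap on chromosome 8 so that their values are uncertain, also had no call. Of 101 cell cycle and histone genes, 65 were higher and 10 lower (66 and 10 adjusted over the list alone), with a median of 0.88 and camera adjusted p = 4.04e-06 (adjusted p = 0.556 with an estimated correlation). Histone H3.3-like (LOC115701521) was at 566 ± 106 against 2.87 ± 0.121 FPKM, and cyclin-A1-1 (LOC115724432), of a class that acts in meiosis, at 324 ± 85.4 against 17 ± 0.681. Among 61 heat shock genes, 37 were higher and 7 lower (37 and 7 adjusted over the list alone), with a median of 0.98 and camera adjusted p = 0.000438 (adjusted p = 0.346 with an estimated correlation). Heat shock 22 kDa protein was at 354 ± 115 against 4.07 ± 0.117 and heat shock protein 83 at 126 ± 28.3 against 1.79 ± 0.008.

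Among lists without a camera call, members moved in both directions. Across 32 ethylene genes, 5 were higher and 14 lower (5 and 14 adjusted over the list alone), with a median of -0.37 and camera adjusted p = 0.0516, or 0.048 with median-ratio scaling. ACC oxidase 5 (LOC115699408) was at 42.6 ± 9.35 against 0.0249 ± 0.0352 FPKM and ETHYLENE INSENSITIVE 3-like 1 (LOC115711236), a transcription factor of ethylene signalling, at 126 ± 13.4 against 23 ± 0.694. Of 33 cytokinin genes, 14 were higher and 9 lower (15 and 9 adjusted over the list alone), with a median of 0.43 and camera adjusted p = 0.269. The LOG-type cytokinin riboside phosphoribohydrolase (LOC115700845), which activates cytokinins, was at 38.4 ± 10 against 0.494 ± 0.0434 and response regulator ARR9 (LOC115700593) at 103 ± 17.6 against 5.74 ± 0.183. Among 37 flowering time and inflorescence genes, 8 were higher and 19 lower (10 and 19 adjusted over the list alone), with a median of -0.44, a mean of 0.03, test direction down and camera adjusted p = 0.176. JOINTLESS was at 63 ± 8.66 against 0.523 ± 0.125 and SVP (LOC115721274) at 28.3 ± 5.85 against 0.0906 ± 0.128 FPKM. Across 31 gibberellin genes, 6 were higher and 13 lower (7 and 13 adjusted over the list alone), with a median of -0.24 and camera adjusted p = 0.185. Snakin-2 (LOC115698303) was at 14.2 ± 1.56 against 159 ± 9.83. Of 31 lipid transfer genes, 7 were higher and 15 lower (7 and 15 adjusted over the list alone), with a median of -0.41, a mean of 0.11, test direction down and camera adjusted p = 0.186. Among 92 pollen and pollen tube cell wall genes, 21 were higher and 39 lower (21 and 41 adjusted over the list alone), with a median of -0.33, a mean of 0.15, test direction down and camera adjusted p = 0.176. A pectinesterase-like gene (LOC115700349) was at 22.8 ± 12.4 against 0.0142 ± 0.02 and INAPERTURATE POLLEN1 (LOC115716968), which shapes pollen apertures, at 39.2 ± 6.01 against 0.922 ± 0.46. Across 81 metal and glutathione genes, 16 were higher and 24 lower (16 and 23 adjusted over the list alone), with a median of -0.15 and camera adjusted p = 0.244. Copper transporter 1-like (LOC115698154) was at 37 ± 0.146 against 0.0705 ± 0.0997. Of 48 photosynthesis genes, 2 were higher and 11 lower (2 and 1 adjusted over the list alone). The median was -0.29 and camera adjusted p = 0.0516, or -0.57 and 0.029 scaled to equal totals, with 2 higher and 29 lower. A Rubisco small subunit gene (LOC115725363) was at 90.6 ± 6.95 against 11.8 ± 1.58. Among 18 circadian clock genes, 4 were higher and 9 lower (4 and 9 adjusted over the list alone), with a median of -0.46 and camera adjusted p = 0.244. REVEILLE 7 (LOC115714271) was higher by 1.31 ± 0.16 and APRR2 (LOC115715581) had a log2 difference of -1.27 ± 0.18.

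In all, 11040 genes differed between male and female week 3 apices in limma, 5796 higher and 5244 lower in male, and 5379 by at least 1 log2 unit. Scaling each library to an equal total moved the median log2 difference of all genes from -0.019 to -0.273 and gave 12377 genes, 4708 higher and 7669 lower.

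**Figure D4:**
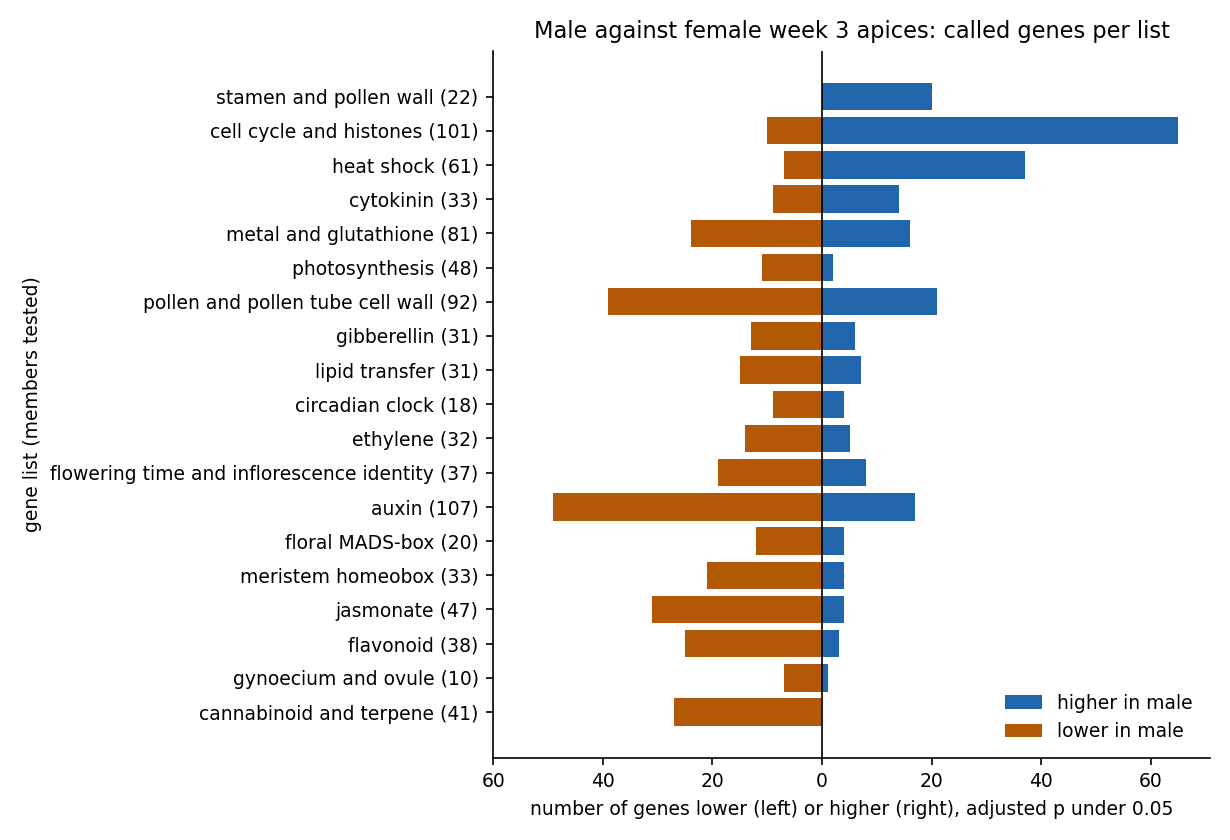
Number of tested members of each of the 19 gene lists that were higher (right) or lower (left) in male than in female week 3 apices at adjusted p under 0.05 in limma, with the number tested after each name. Stamen and pollen wall genes lie to the right with 20 of 22, and cannabinoid and terpene genes to the left with 27 of 41; with libraries scaled to equal totals every list keeps its majority side.

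Female apices between week 1 and week 3 gained transcripts of carpel and ovule genes and lost transcripts of photosynthesis and cell division. The AGAMOUS gene LOC115697576 rose by 4.10 ± 0.26, MADS4 by 3.66 ± 0.23, AGL11 by 2.94 ± 0.22 and CRABS CLAW by 2.13 ± 0.24. The largest rises were germin-like protein 1-17, from 0.489 ± 0.0635 to 311 ± 12.5 FPKM (adjusted p = 2.54e-06), MLP-like protein 34, from 0.25 ± 0.233 to 132 ± 27.4, and a further germin-like gene (LOC115720654), at 73.5 and 72.9 FPKM at week 3 and listed at 0 at week 1. The largest fall was that of mulatexin (LOC115715128), a latex chitin-binding protein, from 502 ± 573 to 0.112 ± 0.0953 FPKM. It was followed by a putative cell wall protein (LOC115700282), from 423 ± 9.76 to 9.75 ± 0.882, and a DEAD-box RNA helicase 9-like gene (LOC133039142), from 817 ± 124 to 36.6 ± 4.9. The adjusted p of the mulatexin gene became 0.112 without female week 1 replicate 1, 0.0943 without female week 3 replicate 1 and 0.0948 without female week 3 replicate 2. Across 20 floral MADS-box genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 2.51 and camera adjusted p = 5.53e-06 (adjusted p = 0.437 with an estimated correlation). Of 10 gynoecium and ovule genes, 7 rose (7 adjusted over the list alone), with a median of 0.78 and camera adjusted p = 0.00197 (adjusted p = 0.335 with an estimated correlation). Among 48 photosynthesis genes, 1 rose and 47 fell (1 and 47 adjusted over the list alone), with a median of -1.46 and camera adjusted p = 3.34e-19 (adjusted p = 0.408 with an estimated correlation). Rubisco small subunit LOC115714527 went from 9420 ± 1670 to 1870 ± 107 FPKM. Across 101 cell cycle and histone genes, 7 rose and 60 fell (9 and 63 adjusted over the list alone), with a median of -0.81 and camera adjusted p = 1.34e-11 (adjusted p = 0.402 with an estimated correlation). Cyclin-D1-1 (LOC115712518) rose by 2.48 ± 0.18, whereas histone H3.2 (LOC115721179) fell by 2.10 ± 0.21. Of 38 flavonoid genes, 20 rose and 3 fell (24 and 4 adjusted over the list alone), with a median of 0.68 and camera adjusted p = 7.82e-05 (adjusted p = 0.335 with an estimated correlation). Dihydroflavonol 4-reductase rose by 3.71 ± 0.30. Among 47 jasmonate genes, 29 rose and 2 fell (32 and 3 adjusted over the list alone), with a median of 0.60 and camera adjusted p = 1.11e-07 (adjusted p = 0.215 with an estimated correlation). TIFY 5A (LOC115696976), a repressor of jasmonate signalling, rose by 3.43 ± 0.25 and linoleate 9S-lipoxygenase 5 LOC115709296 by 3.30 ± 0.25. Across 32 ethylene genes, 14 rose and 2 fell (14 and 2 adjusted over the list alone), with a median of 0.41 and camera adjusted p = 0.00811 (adjusted p = 0.47 with an estimated correlation). The top member, an ACC oxidase homolog (LOC115712349), fell by 2.16 ± 0.16. Of 33 cytokinin genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone), with a median of 0.36 and camera adjusted p = 0.019 (adjusted p = 0.257 with an estimated correlation), or 0.0803 scaled to equal totals. Cytokinin dehydrogenase 3 (LOC115704143), which degrades cytokinins, rose by 3.70 ± 0.18.

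In all, 6438 genes changed in female apices between week 1 and week 3, 3423 higher and 3015 lower, and 2194 by at least 1 log2 unit. The count was 3930 without female week 1 replicate 1, 3752 without female week 3 replicate 1 and 3919 without female week 3 replicate 2. Scaled to equal totals, the median of all genes moved from 0.025 to 0.223 and 7837 genes were called, 5795 higher and 2042 lower, so 73.9% were higher in place of 53.2%. Under that scaling the flowering time list turned from a median of -0.08 to 0.11, circadian clock genes from -0.01 to 0.21 and cannabinoid and terpene genes from -0.08 to 0.13, all without a camera call as deposited.

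Male apices between week 1 and week 3 gained transcripts of stamen identity and pollen wall genes. TM6 went from 1.55 ± 0.935 to 163 ± 9.95 FPKM (log2 change 6.05 ± 0.26), and the AGAMOUS gene LOC115700192 rose by 5.73 ± 0.22 and PMADS 2 by 5.58 ± 0.17. AGL11 fell by 2.19 ± 0.22 and CRABS CLAW fell by 1.97 ± 0.24. Among the largest rises, ATL6-like and MEN-8 were listed at 0 in both male week 1 libraries, M7 rose by 11.31 ± 0.31 and lipid-transfer protein A-like by 10.52 ± 0.23. The largest falls were bark storage protein A (LOC133030849), from 1160 ± 397 to 9.52 ± 2.4 FPKM, GCN5-related N-acetyltransferase 8 (LOC115706319), which fell by 6.64 ± 0.12 log2, and purple acid phosphatase 27 (LOC115709440), from 441 ± 163 to 6.4 ± 2.4. Among 22 stamen and pollen wall genes, 20 rose (20 adjusted over the list alone), with a median of 4.33 and camera adjusted p = 4.53e-10 (adjusted p = 0.037 with an estimated correlation). Polyketide synthase A rose by 9.01 ± 0.15. Across 48 photosynthesis genes, 1 rose and 44 fell (1 and 44 adjusted over the list alone), with a median of -1.35 and camera adjusted p = 1.07e-10 (adjusted p = 0.531 with an estimated correlation). Of 41 cannabinoid and terpene genes, 21 fell (21 adjusted over the list alone), with a median of -0.56 and camera adjusted p = 3.79e-05 (adjusted p = 0.215 with an estimated correlation). Alpha-humulene synthase (LOC115724563) fell by 3.47 ± 0.18. Among 61 heat shock genes, 34 rose and 9 fell (34 and 9 adjusted over the list alone), with a median of 0.74 and camera adjusted p = 0.00618 (adjusted p = 0.464 with an estimated correlation). Heat shock 22 kDa protein rose by 7.12 ± 0.33. Across 33 cytokinin genes, 20 rose and 4 fell (20 and 6 adjusted over the list alone), with a median of 1.02 and camera adjusted p = 0.00928 (adjusted p = 0.215 with an estimated correlation). Of 33 meristem homeobox genes, 4 rose and 18 fell (4 and 18 adjusted over the list alone), with a median of -0.63 and camera adjusted p = 0.00532 (adjusted p = 0.397 with an estimated correlation). WUSCHEL rose by 2.17 ± 0.25. Among 20 floral MADS-box genes, 11 rose and 4 fell (11 and 4 adjusted over the list alone), with a median of 0.67 and camera adjusted p = 0.176. Across 31 lipid transfer genes, 9 rose and 13 fell (9 and 14 adjusted over the list alone), with a median of -0.50, a mean of 0.61, test direction down and camera adjusted p = 0.292. Allene oxide synthase 3 went from 191 ± 23.5 to 6.44 ± 1.19 FPKM, JOINTLESS rose by 2.99 ± 0.16, and SOC1 (LOC115706939), a promoter of flowering, fell by 2.48 ± 0.21.

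In all, 11303 genes changed in male apices between week 1 and week 3, 6190 higher and 5113 lower, and 5754 by at least 1 log2 unit. Of these, 1498 higher and 1966 lower genes were shared with the change in female apices, where independent lists would share 1157.3 and 842.0, and 960 went in opposite directions; this overlap was chosen after the data were seen.

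Week 3 apices were also compared with vegetative apices. In female apices early nodulin-75 went from 1.61 ± 2.27 to 622 ± 60.7 FPKM (log2 change 8.24 ± 0.58, adjusted p = 4.79e-05), germin-like protein 1-17 rose by 8.14 ± 0.38 and RD22 (LOC115719008) went from 0.396 ± 0.471 to 246 ± 42.7. Mulatexin LOC115715128 went from 2760 ± 320 to 0.112 ± 0.0953 FPKM (log2 change -11.27 ± 1.85). Of 48 photosynthesis genes, 48 fell (48 adjusted over the list alone), with a median of -1.57 and camera adjusted p = 2.13e-20 (adjusted p = 0.397 with an estimated correlation). Among 20 floral MADS-box genes, 15 rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 3.63 and camera adjusted p = 9.4e-09 (adjusted p = 0.341 with an estimated correlation). The top members were CAULIFLOWER, by 5.88 ± 0.34, and the AGAMOUS gene LOC115697576, by 5.85 ± 0.26, while PMADS 2 fell by 1.57 ± 0.17. SVP went from 29.1 ± 0.563 to 0.0906 ± 0.128 and JOINTLESS fell by 4.10 ± 0.16. Across 38 flavonoid genes, 24 rose and 4 fell (25 and 5 adjusted over the list alone), with a median of 0.74 and camera adjusted p = 4.33e-05 (adjusted p = 0.335 with an estimated correlation). Of 61 heat shock genes, 5 rose and 28 fell (5 and 29 adjusted over the list alone), with a median of -0.43 and camera adjusted p = 4.33e-05 (adjusted p = 0.335 with an estimated correlation). Among 101 cell cycle and histone genes, 10 rose and 32 fell (11 and 38 adjusted over the list alone), with a median of -0.36 and camera adjusted p = 0.000293 (adjusted p = 0.619 with an estimated correlation). Across 47 jasmonate genes, 24 rose and 8 fell (26 and 9 adjusted over the list alone), with a median of 0.45 and camera adjusted p = 0.00616 (adjusted p = 0.341 with an estimated correlation). Of 32 ethylene genes, 13 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.43 and camera adjusted p = 0.00645 (adjusted p = 0.47 with an estimated correlation). Among 33 cytokinin genes, 16 rose and 4 fell (17 and 4 adjusted over the list alone), with a median of 0.44 and camera adjusted p = 0.00717 (adjusted p = 0.215 with an estimated correlation), or 0.0507 scaled to equal totals. Across 10 gynoecium and ovule genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.45 and camera adjusted p = 0.0153 (adjusted p = 0.397 with an estimated correlation). Of 33 meristem homeobox genes, 12 rose and 1 fell (12 and 2 adjusted over the list alone), with a median of 0.50 and camera adjusted p = 0.0175 (adjusted p = 0.465 with an estimated correlation), or 0.0575 scaled to equal totals. In all, 6690 genes changed, 3623 higher and 3067 lower, and 2326 by at least 1 log2 unit. The count of changed genes was 4415 without vegetative replicate 2, 4071 without female week 3 replicate 1 and 4015 without female week 3 replicate 2. Scaled to equal totals, the median of all genes moved from 0.015 to 0.217 and 7823 genes were called, 5891 higher and 1932 lower.

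In male week 3 against vegetative apices, ATL6-like rose by 11.50 ± 0.15, MEN-8 by 11.24 ± 0.31 and M7 by 11.08 ± 0.31. Mulatexin LOC115715128 went from 2760 ± 320 to 0.456 ± 0.474 FPKM and bark storage protein A from 1520 ± 219 to 9.52 ± 2.4. TM6 rose by 7.07 ± 0.26, whereas AGL11 was at 1.01 ± 0.226 FPKM in male week 3 and 0.818 ± 0.432 in vegetative apices (adjusted p = 0.548). Among 22 stamen and pollen wall genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 4.32 and camera adjusted p = 1.44e-09 (adjusted p = 0.037 with an estimated correlation). Across 48 photosynthesis genes, 1 rose and 45 fell (1 and 47 adjusted over the list alone), with a median of -1.91 and camera adjusted p = 9.3e-14 (adjusted p = 0.47 with an estimated correlation). Of 20 floral MADS-box genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 2.96 and camera adjusted p = 4.44e-05 (adjusted p = 0.47 with an estimated correlation). Among 41 cannabinoid and terpene genes, 1 rose and 21 fell (1 and 20 adjusted over the list alone), with a median of -0.70 and camera adjusted p = 0.000333 (adjusted p = 0.269 with an estimated correlation). Alpha-humulene synthase LOC115724563 fell by 2.89 ± 0.18. Across 33 cytokinin genes, 21 rose and 4 fell (21 and 5 adjusted over the list alone), with a median of 1.08 and camera adjusted p = 0.00535 (adjusted p = 0.215 with an estimated correlation). Of 101 cell cycle and histone genes, 58 rose and 19 fell (61 and 19 adjusted over the list alone), with a median of 0.65 and camera adjusted p = 0.00548 (adjusted p = 0.656 with an estimated correlation). Among 47 jasmonate genes, 11 rose and 23 fell (11 and 23 adjusted over the list alone), with a median of -0.41 and camera adjusted p = 0.0057 (adjusted p = 0.341 with an estimated correlation). In all, 11492 genes changed, 6375 higher and 5117 lower, and 5888 by at least 1 log2 unit.

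Whether the difference between male and female apices changed from week 1 to week 3 was tested directly, as an interaction. It did in 8356 genes, 4720 with a higher and 3636 with a lower male level relative to female at week 3, and 5323 by at least 1 log2 unit. The ferredoxin-NADP reductase LOC115695589 had the largest value, 11.76 ± 0.52 log2. It was lower in male apices at week 1 and at 741 ± 479 FPKM against 0.036 ± 0.051 at week 3. Of the 22 stamen and pollen wall genes the male level rose relative to female in 20, and of 41 cannabinoid and terpene genes it fell in 24 and of 47 jasmonate genes in 27, with 4 higher (20, 24 and 28, with 4 higher, adjusted over the list alone). These lists had camera adjusted p of 8.75e-13, 9.61e-07 and 1.39e-06 (adjusted p = 0.037, 0.215 and 0.215 with an estimated correlation). Of 20 floral MADS-box genes, 4 were higher and 11 lower (4 and 13 adjusted over the list alone; camera adjusted p = 0.0209, adjusted p = 0.619 with an estimated correlation and 0.0964 after scaling to equal totals). Scaled to equal totals, 9428 genes were called, 3905 higher and 5523 lower, so 41.4% were higher in place of 56.5%. Of the 25 genes called at week 1, 5 of the 22 higher genes were also higher at week 3 (7.0 by independence, Fisher exact p = 0.493), 1 of the 3 lower genes was also lower (0.9 by independence, Fisher exact p = 1), and 11 went the other way. Those shared were the salicylate and benzoate methyltransferase LOC115711939, acidic endochitinase, lysine histidine transporter-like 7, LOC133033235 and LOC115700763, and, among lower genes, RADIALIS-like 2, all named after their values were seen. The methyltransferase was at 14.7 ± 3.86 against 1.56 ± 0.0636 FPKM in male against female week 3 apices.

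The authors' deposited table also holds a log2 fold change and an adjusted p per gene for each pair of groups. At adjusted p under 0.05 the authors' deposited table called 54 genes between male and female at week 1, 47 higher and 7 lower, of which 19 were among the 25 called in limma. At week 3 the authors' deposited table called 10356, with 9803 shared. Against vegetative apices the authors' deposited table called 1335 in female week 1 (791 shared), 810 in male week 1 (735 shared), 6991 in female week 3 (6000 shared) and 10138 in male week 3 (9883 shared). Between weeks the authors' deposited table called 7439 in female (6018 shared) and 9158 in male apices (9012 shared). All shared genes had the same direction in the authors' deposited table and in limma, and the log2 fold changes correlated between 0.915 and 0.945 across genes.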

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

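The interaction and the 19 gene lists were planned, and the salicylate list below was not among the 19. The test of the salicylate list without the called genes was set out before its result was seen. So was that of the share of photosynthesis genes in the gap of total FPKM. All other tests of explanations below were chosen after the result was seen.

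The difference between male and female apices changed from week 1 to week 3 in 8356 genes, in limma's test of the interaction. Larger in male apices at week 3 were the ferredoxin-NADP reductase LOC115695589 (11.76 log2), ATL6-like LOC115718105 (11.68), MEN-8 LOC115715872 (11.32), M7 LOC115718067 (10.86) and class V chitinase LOC115695573 (10.51). Larger in female apices were LOC115721564 (-10.17), lipid-transfer protein 1 LOC115696872 (-9.09), germin-like protein 1-17 LOC115718819 (-8.47), an MLP-like gene LOC115699451 (-7.32) and the proline-rich extensin-like gene EPR1 LOC115722580 (-7.01). LOC115721564, which has no description, was at 1150 ± 21.3 FPKM in female week 3 apices and listed at 0 in the other 8 libraries, and ATL6-like and MEN-8 were listed at 0 in male week 1 libraries, so these values depend on the pseudocount.

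Gene lists also differed between the weeks in camera, with medians of 4.31 for stamen and pollen wall, 0.96 for heat shock and 0.65 for cell cycle and histone genes. Medians were -0.49 for auxin, -1 for cannabinoid and terpene, -1 for jasmonate, -1.09 for flavonoid, -1.32 for floral MADS-box, -1.45 for gynoecium and ovule and -0.83 for meristem homeobox genes. Of these, the stamen and pollen wall list alone kept its call with an estimated correlation (adjusted p = 0.037). The adjusted p of the others was then 0.341 for heat shock, 0.617 for cell cycle, 0.257 for auxin, 0.215 for cannabinoid and terpene and for jasmonate, 0.332 for flavonoid, 0.619 for floral MADS-box, and 0.341 for gynoecium and ovule and for meristem homeobox genes.

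The 2 male week 1 libraries differed from each other more than the 2 female ones, at 32.2 and -15.3 on the fourth principal component, with female libraries at -20.6 and -1.1. A wrong label on male replicate 2 was not decided. In 18 genes (7 by 2 units), both male libraries lay at least 1 log2 unit to 1 side of both female ones. The gap also exceeded that between replicates of other groups. Pairing male replicate 1 with female replicate 1 or 2 gave 0 and 5 (0 and 2). That condition was added last, after other tests had not decided. Without it, counts were 19, 3 and 6 (8, 2 and 3 by 2 units). With the female mean on both sides, 79.1% and 93.8% of genes called with 1 male library lay on that side in the other. By 1 log2 unit, 23.3% and 68.8% did. With no library shared, male replicate 2 lay on the side called with replicate 1 in 34.1% or 60.9% of genes. Against lower depth as the whole cause, the spread between replicates was 1.56 times that of female libraries (SD 0.425 against 0.273) over 9929 genes of at least 10 FPKM. A different share of green tissue may contribute: photosynthesis genes differed between the male libraries by a median of -0.57, with 97.9% of the 48 on 1 side, where the next list differed by 0.47 (floral MADS-box) and the female libraries by 0.33 in the same genes; a difference between plants was not tested.

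Genes known from salicylate defence were higher in male week 1 apices. Of 37 tested genes closest to 1 of 38 Arabidopsis salicylate genes, many sharing a match, 7 were called higher. As in a wider response, the 30 not called lay above other genes in camera (p = 0.015, or 0.0516 with an estimated correlation). The 30 had a median of only 0.06, with 18 above 0. Both male libraries lay above both female ones in all 7 called genes, but these were selected using both. Medians of 0.09 and 0.04 in the other 30 did not decide if 1 library was the source. The silver thiosulfate treatment and male development cannot be told apart, since every male library was treated; at week 3 the list had a median of -0.47, with 7 of 37 members higher and 15 lower.

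Totals of FPKM were 14.7% lower in female week 3 than in female week 1 libraries (617210 against 723486). Photosynthesis genes held 26.3% of the gap, falling from 5.8% to 2.3% of the total, the 10 highest genes 16.3% and the 292 ribosomal protein genes 25.2%. A first search for ribosomal genes had matched few of them and was widened. None of these shares accounts for the whole gap, and the rest may lie in gene length or in the authors' normalisation, neither of which was tested.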

How the results depend on the processing

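The 2 scalings (median ratios and equal totals), the split of the vegetative libraries and the overlap of changes between weeks were chosen after the data were seen; the other alternatives had been planned. Alternatives that need counts, DESeq2 and another normalization factor, were not run because the table holds FPKM, and the counts of values near 0 rest on few reads at an unknown depth. With 2 libraries per group, a fit without 1 library leaves a lone library that is assumed to vary like the other groups.

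Male against female at week 1 was the least stable comparison. Its 25 genes became 16 with a pseudocount of 0.1 and 5 with no filter on low values, where more genes were adjusted for. A limma fit of only the 4 libraries called 0. Without 1 library the count ran from 5 to 86. Other counts moved by more than 1.5 times when only the groups compared were fitted, with fewer libraries to estimate the spread: 394 in female week 1 against vegetative (from 904) and 8 in male week 1 against vegetative apices (from 1172). Leaving out 1 library gave 230 to 502 in female week 1 and 658 to 1531 in male week 1 against vegetative, 4015 to 5249 in female week 3 against vegetative and 3752 to 4460 in female week 3 against week 1. It gave 8980 to 10029 in male against female week 3, 9938 to 10495 in male week 3 against vegetative, 10039 to 10944 in male week 3 against week 1 and 6731 to 8448 in the interaction, each within 1.5 times. The causes were not tested.

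Asking for at least 1 log2 unit, which by construction keeps a part of the calls, left 389 genes in female week 1, 504 in male week 1, 2326 in female week 3 and 5888 in male week 3 against vegetative apices. It left 5379 in male against female week 3, 2194 and 5754 in female and male week 3 against week 1, and 5323 in the interaction. Overlaps became 2 (from 6) between week 1 and week 3 for male against female, 299 (from 653) between female and male week 1 against vegetative, and 1027 (from 3464) between the changes of female and male apices across weeks. With 1 vegetative library for each sex, the overlap of 653 became 244 and 298, where fewer genes were called in each. Of 67 camera calls of lists, 4 were left with an estimated correlation, which widens the null, and fry made 92 calls, 59 of them shared. List medians that changed sign under a scaling belonged to lists without a camera call.

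Same-numbered replicates did not deviate together: of 10 correlations of deviations, 2 were above 0.1, and they ran from -0.42 to 0.21, so the labels' numbers were not taken as pairs. With the replicate block the counts were 20 in male against female week 1, 10837 at week 3, 773, 990, 6242 and 11277 in female week 1, male week 1, female week 3 and male week 3 against vegetative, 6056 and 11081 in female and male week 3 against week 1, and 8089 in the interaction. Overlaps with the block were 6, 572 and 3270, and camera made 68 calls, 67 of them shared; none moved by 1.5 times.

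Of 404 values of named genes, 345 were called, 280 of these in every alternative and 65 not in at least 1, and no call changed sign. Calls were lost for 12 with the pseudocount and gained for 6, lost for 18 without the filter, 53 with only the groups compared (gained for 2), 5 with the block, 3 with median ratios and 4 with equal totals (gained for 3). Over 1656 values in fits without 1 library, 91 calls were lost and 8 gained.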

Other observations

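Some genes outside the fixed lists, picked after the values were seen, also changed strongly. Galactinol synthase 2 (LOC115719672), which starts the synthesis of raffinose sugars, was at 83.1 ± 11.2 FPKM in female week 3 and 1.06 ± 0.0225 in female week 1 apices (log2 change 5.35 ± 0.24). Laccase-15 (LOC115705062), of a family of lignin and flavonoid oxidases, was at 45.8 ± 7.24 and 0.225 ± 0.272 FPKM (log2 change 5.27 ± 0.23). Ferritin-like catalase Nec2 (LOC115723057) fell by 3.82 ± 0.23 over the same interval and patatin-like protein 2 (LOC115696747) fell by 4.26 ± 0.27. Acid phosphatase 1 (LOC115707554) was at 4560 ± 185 FPKM in vegetative and 87.9 ± 0.0433 FPKM in male week 3 apices, and ribonuclease 3 (LOC115721896) was at 742 ± 64.8 and 12.8 ± 2.09 FPKM.

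Mulatexin LOC115715128 varied widely between replicates of female week 1, at 907 and 96.2 FPKM, with a mean of 2760 ± 320 FPKM in vegetative apices.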
